A study of Staphylococcus aureus with 17 samples.

How the data were processed

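RNA from Staphylococcus aureus strain ATCC29213 was compared on two-colour spotted arrays, with RNA of a treated culture in one channel and RNA of an untreated culture in the other. Per the labels, the untreated RNA was collected at the density at which treatment began, so it was not matched in time to the treated samples. Each ratio against untreated therefore includes any change with time in culture besides the effect of the compound. The labels do not say whether groups or replicates shared untreated RNA. The series' design text states biological replicates. The 17 samples comprised 34 arrays, a dye-swapped pair for each sample. Of these, 15 samples in 5 groups of 3 were on one platform with 4 spots per probe and 4272 locus tags, and the 2 CCCP samples were on another platform with 3 spots per probe and 4358 tags.

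The scanner files deposited by the authors hold spot intensity in Cy3 and Cy5, per the file headers. Most control spots without a bacterial probe were at exactly 0 in Cy5, so the intensities were taken as background-corrected with a floor at 0, and no further background correction was applied. The spot-finding software is not given in the sources used here. The deposited value tables hold 1 log2 ratio per sample whose scale, centring and direction the sources do not state. Set against the scanner values of the same sample, their columns had correlations across tags of 0.908 to 0.971, slopes of 0.836 to 0.918 and medians of -0.07 to 0.15. The method by which the authors made them stays unknown. Rows of the CCCP table were matched to tags through the probe identifiers of the larger platform, because they correlated with the scanner values that way.

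The labels name both dyes for both channels and do not settle which dye held the treated RNA. The names of the deposited arrays do, and ratios were turned to treated over untreated by them, a direction that is therefore likely rather than stated by the labels. The ratio column deposited by the authors was treated over untreated by that naming on 32 arrays, within 2%, and the inverse on the 2 arrays of CCCP replicate 1. Turned by name, both CCCP samples correlated at 0.84 across 1669 tags and the deposited table had the same sign as the values used here.

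Spots at 0 in either channel and control spots were left out. Each array was normalized by loess (span 0.3, 4 iterations) with limma 3.58.1 in R 4.3.3. Spots of a probe were averaged, then the 2 arrays of a sample, with both dye orientations required. A tag with more than 1 probe, which was the case for 86 tags of the larger platform, was represented by its brightest probe. Probes of a tag were called in opposite directions for 1 tag each after vancomycin, enduracidin 15 min and enduracidin 60 min, when all probes were tested. Ratios were obtained for 1602 to 2675 tags per sample on the larger platform and for 1789 and 2139 tags in the CCCP samples. On the larger platform 32.9% to 64.4% of probe spots had signal in both channels. The number of arrays limits the precision.

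Samples within a group were compared before they were averaged. The variance of the difference between samples was divided by the technical variance between their dye-swapped arrays. This ratio was 0.540 for telavancin 60 min replicates 2 and 3 and 0.313 for enduracidin 60 min replicates 1 and 2, and 1.25 to 9.78 for the other pairs. The close samples were therefore averaged and counted as 1 replicate, which left 13 replicates, 2 of them in each of these groups. The design fixed before the data were examined had counted all 15 samples. Counting the close samples as 1 was chosen after the counts under both had been computed, and the counts with all 15 samples are given among the alternatives.

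Group means of log2(treated/untreated) were tested against 0, and differences between group means against each other, with limma's lmFit and eBayes and Benjamini-Hochberg adjustment at 0.05, on tags with a ratio in at least 2 replicates of each group compared. All groups of the larger platform shared one estimate of the spread, and the CCCP samples were fitted alone. If replicates shared untreated RNA, which the labels leave open, a ratio tested against 0 leaves out the spread of the untreated control. Errors given with log2 values are the model's standard errors. They borrow spread from other tags and, on the larger platform, other groups, so the SD between samples could be larger or smaller. It was 2.87 for SACOL1124 after CCCP and 0.0502 for MW2444 after telavancin 60 min (n = 2 each). On simulated data with the real pattern of measured values and 200 changed tags, the fit of telavancin 15 min against untreated, on 1873 tags, recovered 71% of 2-fold and all of the 4-fold changes, and that of telavancin 60 min against vancomycin 60 min, on 1780 tags, recovered 24% and 87%. For the interaction of time and compound, on 1528 tags, 10% and 57% were recovered. For CCCP, on 1669 tags, 32% and 99% were recovered. The simulated spread of each tag was the moderated estimate of the fit. An earlier simulation that used each tag's own unmoderated spread recovered fewer of the 4-fold changes in each comparison, and no change for CCCP, so these shares depend on that choice.

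The arrays list locus tags without gene names. None of their 4361 tags matched the reference gene table, whose assembly is ASM1342v1, so no member of the 25 gene lists fixed beforehand could be found and the gene list tests were not made. Tags are given as the files give them, and the files do not pair them with names or functions. By the rule fixed beforehand, the 2 highest and the 2 lowest mean ratios past the threshold with the same sign in every sample are named for each comparison against untreated; for differences between groups, the 2 highest and 2 lowest are named. Alternatives were other normalizations, single dye orientations, the deposited value tables, another variance model, a fold threshold, a replicate block, fits of the compared groups alone and leaving out each sample.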

Results

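The data are expression ratios of S. aureus cultures treated with 4 compounds against untreated culture. The untreated culture was collected at the density at which treatment began. Changes against untreated therefore include any change with time in culture. Telavancin, a semisynthetic lipophilic derivative of the glycopeptide vancomycin, was given at 8 µg/ml for 15 or 60 min. Vancomycin, which blocks cell wall synthesis by binding its precursors, was given at 10 µg/ml for 60 min. Enduracidin, a lipopeptide inhibitor of cell wall synthesis, was given at 1 µg/ml for 15 or 60 min, and CCCP, a protonophore that dissipates the proton gradient across the membrane, at 2 µg/ml for 15 min. Each group had 3 labelled samples, except CCCP with 2. Replicates 2 and 3 of telavancin 60 min, and replicates 1 and 2 of enduracidin 60 min, differed by less than the technical noise between dye-swapped arrays and were each counted as 1 sample, so that these groups had n = 2.

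Telavancin for 15 min changed 694 of 1873 locus tags, 373 higher and 321 lower than untreated. SACOL0625 rose by a log2 ratio of 7.25 ± 0.54 (SE, n = 3) and SAV2702 by 6.50 ± 0.60 (SE, n = 2). SAV0226, at -3.77 ± 0.76, and SAV2366, at -3.74 ± 0.52 (SE, n = 2 each), were the lowest. At least 2-fold changes were called for 404 tags. Without telavancin 15 min replicate 2 or 3, 443 or 395 tags were called, and the deposited value table gave 386.

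Telavancin for 60 min changed 948 of 1911 tags, 459 higher and 489 lower. SAV2702 rose by 7.99 ± 0.61 and SAV2701 by 7.81 ± 0.40, while SACOL0222 stood at -7.26 ± 0.52 and SACOL2491 at -6.51 ± 0.43 (SE, n = 2 each). Changes of at least 2-fold numbered 362 higher and 388 lower. Replicate 1 correlated with the mean of the others at 0.749 across tags, and without it 969 tags were called, the lone remaining replicate being assumed, here and in later comparisons, to vary like the other groups. The fit of this group alone called 553 tags, spots above the control spots only 626, and 589 were called with the values deposited by the authors.

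Vancomycin for 60 min changed 906 of 2011 tags, 442 higher and 464 lower. SAV2556 rose by 6.34 ± 0.52 (SE, n = 3) and SAS1587 by 5.82 ± 0.75 (SE, n = 2). SAV2514, at -4.56 ± 0.48 (SE, n = 2), and SAV0226, at -4.51 ± 0.62 (SE, n = 3), were the lowest. At least 2-fold changes were called for 576 tags, and the deposited value table gave 481. Without vancomycin replicate 1 or 2 the count was 601 or 547.

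Enduracidin for 15 min changed 684 of 2224 tags, 386 higher and 298 lower. SAV2702 rose by 6.50 ± 0.49 (SE, n = 3) and SAS2586 by 6.30 ± 0.38 (SE, n = 2). SACOL2491, at -4.26 ± 0.43 (SE, n = 2), and SAV1069, at -3.24 ± 0.53 (SE, n = 3), were the lowest. At least 2-fold changes numbered 400, the deposited value table gave 354 and the fit of this group alone 1051. Without enduracidin 15 min replicate 2 or 3, 263 or 280 tags were called.

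Enduracidin for 60 min changed 967 of 2064 tags, 441 higher and 526 lower. SAV2556 rose by 6.70 ± 0.65 and SAV2703 by 6.57 ± 0.55, while SAV2397 stood at -4.87 ± 0.95 and SACOL1075 at -4.76 ± 0.68 (SE, n = 2 each). Changes of at least 2-fold numbered 321 higher and 406 lower. The deposited value table gave 557 tags. Its columns of replicates 2 and 3 match the arrays of each other, so that replicates 1 and 2 of the table join other arrays than the close ones, and with these columns exchanged it gave 543. Further, 538 were called without enduracidin 60 min replicate 3, where the lone remaining replicate, here and in later comparisons, was assumed to vary like the other groups.

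CCCP for 15 min changed 694 of 1669 tags, 369 higher and 325 lower, nearly all of them at least 2-fold (691 tags). SAV2420 rose by 6.01 ± 0.36 and SAR0996 by 5.57 ± 0.29, while SACOL1124 stood at -5.13 ± 0.97 and SAV0213 at -4.46 ± 0.33 (SE, n = 2 each). The direction was taken from the names of the arrays. The deposited ratio column of replicate 1 ran the opposite way, and that of replicate 2 ran the same way as the names. Turned the other way, the counts would be 325 higher and 369 lower. The deposited value table gave 340 tags, spots above the control spots only 347 and spots at 0 kept at a floor 460.

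Telavancin and vancomycin, its parent compound, were compared at 60 min, at 8 and 10 µg/ml. They differed for 229 of 1780 tags, 86 higher and 143 lower after telavancin. SAV0975 was at 4.01 ± 0.24 (SD, n = 2) after telavancin and 0.28 ± 0.44 (SD, n = 2) after vancomycin, a difference of 3.73 ± 0.47 (SE). SAV2702 differed by 3.62 ± 0.86. MW2444 was lower after telavancin by -3.86 ± 0.49 and SACOL0222 by -3.71 ± 0.67. Among the tags tested, 329 had a 95% interval of the difference within 2-fold, and the median half-width of the interval was 0.84 on the log2 scale. Only 4 tags were called when these groups were fitted alone, 110 with the deposited value table (67 higher and 43 lower) and 129 without vancomycin replicate 2. With all 15 samples counted, 362 tags were called.

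Telavancin at 8 µg/ml and enduracidin at 1 µg/ml differed at 60 min for 8 of 1719 tags, 4 higher and 4 lower after telavancin. SAV0175 differed by 2.52 ± 0.39 and SAV1396 by 2.42 ± 0.39, and SAS0164 by -2.31 ± 0.41 and SAV0329 by -1.93 ± 0.36, each with an adjusted p of 0.0434 by limma. The interval of the difference lay within 2-fold for 330 tags. No tag was called when the groups were fitted alone, without telavancin 60 min replicate 1 or 2, enduracidin 60 min replicate 2 or 3, vancomycin replicate 1 or 2 or any one of the 15 min samples of telavancin or enduracidin, 4 were called without telavancin 60 min replicate 3, 7 with the deposited value table and 1 with its enduracidin 60 min columns exchanged, and 67 were called with all 15 samples counted. At 15 min no tag of 1767 differed between the same compounds and doses by limma, with 76 at an unadjusted p below 0.05, while a fit of these groups alone called 13, 7 higher and 6 lower after telavancin. There the interval lay within 2-fold for 917 tags, with a median half-width of 0.75. Without telavancin 60 min replicate 1, vancomycin replicate 3 or telavancin 15 min replicate 1, the counts were 10, 4 and 1, through the shared estimate of the spread or the group mean.

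Vancomycin at 10 µg/ml and enduracidin at 1 µg/ml differed at 60 min for 121 of 1820 tags, 46 higher and 75 lower after vancomycin. SACOL0690 was higher by 3.59 ± 0.44 and SACOL0689 by 3.18 ± 0.60. SAV2330 was lower, at -2.50 ± 0.78 (SD, n = 3) after vancomycin and 1.15 ± 0.63 (SD, n = 2) after enduracidin, and SAV2671 differed by -3.58 ± 0.43 (SE). The interval of the difference lay within 2-fold for 419 tags. Without enduracidin 60 min replicate 3, vancomycin replicate 2, or telavancin 60 min replicate 1, the counts were 32, 68 and 224, without enduracidin 15 min replicate 2 or 3 they were 77 or 76, and with all 15 samples counted 282. The deposited value table gave 83, and 56 with its enduracidin 60 min columns exchanged. The balance of directions was not kept, with 146 higher and 136 lower when all 15 samples were counted, 140 and 124 when a replicate block was added, and 112 and 112 without telavancin 60 min replicate 1.

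Between 15 and 60 min of telavancin, 399 of 1678 tags changed, 140 higher and 259 lower at 60 min. SAV2419 rose by 3.51 ± 0.69 and SAV2205 by 3.39 ± 0.47, while SACOL0222 moved by -4.33 ± 0.73 and SACOL0689 by -4.18 ± 0.60. In that order, their SDs between samples after telavancin 60 min were 0.85, 1.02, 1.32 and 2.01 (n = 2 each). Between 15 and 60 min of enduracidin, 211 of 1938 tags changed, 72 higher and 139 lower. SAS2048 rose by 2.94 ± 0.34 and SAR0996 by 2.80 ± 0.52, while SAS2285 moved by -4.16 ± 0.49 and SAV2395 by -3.88 ± 0.99. The untreated RNA was not matched in time, so these differences include any change with time in culture. The median difference over all tags was -0.16 for telavancin and -0.12 for enduracidin, and 0.01 and 0.03 with the deposited value table, which called 108 higher and 89 lower for telavancin and 60 higher and 62 lower for enduracidin, or 49 higher and 44 lower with its enduracidin 60 min columns exchanged. With all 15 samples counted, 604 tags were called for telavancin and 414 for enduracidin. For telavancin 265 tags were called without 15 min replicate 3 and 125 in a fit of these groups alone. For enduracidin 129, 101 and 79 were called without 15 min replicates 1, 2 and 3, 75 without 60 min replicate 3, 350 without telavancin 60 min replicate 1 and 640 in a fit of these groups alone.

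The change from 15 to 60 min differed between telavancin and enduracidin for none of 1528 tags by limma, with 95 at an unadjusted p below 0.05. The median half-width of the interval of this difference was 1.15, and 40 tags had an interval within 2-fold. With all 15 samples counted, 3 tags were called.

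Group means of the log2 ratio correlated across tags between every pair of groups, although tags are not independent replicates. Pearson's r was 0.902 (rho 0.895) between telavancin and enduracidin at 15 min and 0.895 (rho 0.872) at 60 min. Between telavancin and vancomycin at 60 min r was 0.804 (rho 0.769), and between vancomycin and enduracidin at 60 min 0.816 (rho 0.760). With CCCP, r was 0.473 for telavancin 60 min, 0.459 for enduracidin 60 min, 0.310 for enduracidin 15 min, 0.265 for telavancin 15 min and 0.226 for vancomycin. These follow the direction given by the names of the CCCP arrays. Turned the other way, each has the opposite sign, from -0.473 to -0.226, and tags shared with CCCP become opposite ones. If 50% of the variance of each group mean came from shared untreated RNA, simulated groups without any effect gave r of 0.496 to 0.502 on the larger platform and 0.469 to 0.475 with CCCP, where each r found was below the simulated one for its pair. The simulated r mainly follows this share, which was chosen and not estimated, so that order decides nothing. The plan had been to take the share from the residual correlation between groups. The simulated covariance was 0.0375 to 0.0550, against 0.816 to 1.74 between groups of the larger platform and 0.355 to 1.02 with CCCP. The simulated value is bounded by the spread between replicates, which leaves out untreated RNA shared by those replicates. The gap therefore does not limit what such sharing could give. With CCCP, vancomycin shared 102 higher and 98 lower tags, against 67.0 and 78.4 for independent lists, and 120 were called in opposite directions, against 146.5. Telavancin 60 min shared 139 and 136 with CCCP, against 77.5 and 80.7, with 59 opposite, against 158.6. Telavancin and enduracidin at 15 min shared 269 higher and 195 lower tags, against 68.1 and 43.8 for independent lists. Of 1505 tags tested in all 5 groups of the larger platform, 135 were higher and 93 lower in every group, against 0.866 and 0.631 for independent lists. Part of each excess may come from shared untreated RNA, which the labels do not describe. Each ratio also includes any change with time in culture, as the untreated RNA was not matched in time. How much of the correlations and shared calls comes from such a change was not tested.

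**Figure D1:**
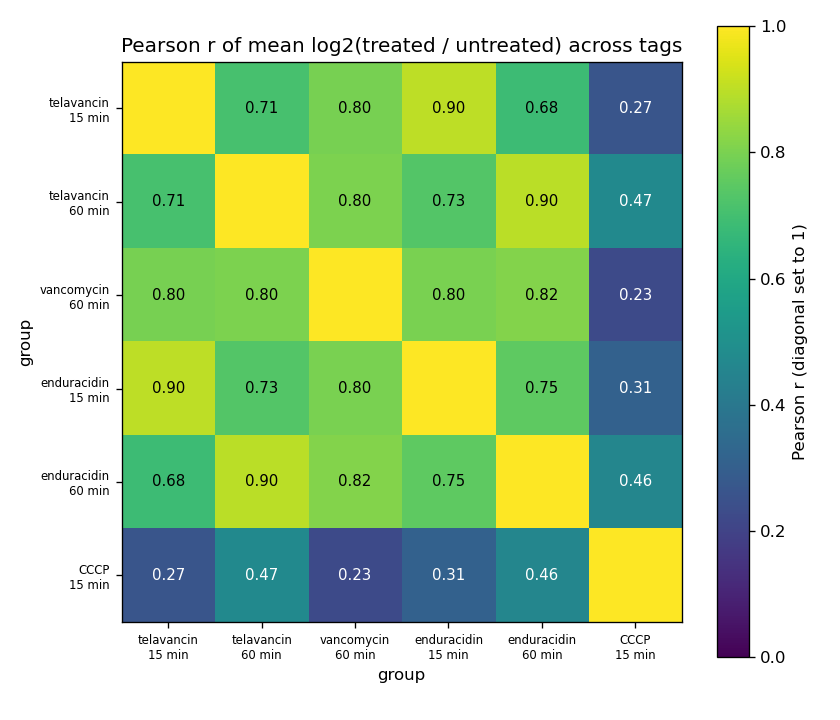
Pearson r across locus tags between the mean log2 ratios of each pair of the 6 groups, which label both axes, with colour and number giving r. The highest values are those of telavancin with enduracidin at 15 min, 0.902, and at 60 min, 0.895, and the smallest in size is that of vancomycin with CCCP, 0.226. Values with CCCP change sign if its direction is turned.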

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

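The tests of the close samples, of the origin of telavancin 60 min replicate 1 as a sample of another group, and of the CCCP-rising tags alone were chosen after the results were seen. The differences between groups were tested directly with limma. Telavancin and vancomycin at 60 min differed for 229 tags, telavancin and enduracidin at 60 min for 8, vancomycin and enduracidin for 121, the times of telavancin for 399 and the times of enduracidin for 211.

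Control spots without a bacterial probe gave signal in Cy3 on a median of 26.5% of spots per array of the larger platform and 29.8% of the CCCP platform, against 7.92% and 3.33% in Cy5. Signal on at least 50% of the spots in the treated channel of every array, and on fewer in the untreated channel of every array, was seen for 1 tag after telavancin 15 min (SAV0460), 3 after telavancin 60 min (SAV0361 and SAV2057 among them) and 1 after enduracidin 60 min (SAR1921), and the opposite for 0 tags in these groups. After CCCP, whose direction rests on the names of the arrays, 4 tags met this rule and 24 met its opposite. With no spot allowed in the other channel, the counts were 0 in the groups of the larger platform, and 1 and 12 after CCCP. SAV0460 had a ratio in 2 samples and was tested, while the others had one in at most 1 sample of their group and were not tested against untreated there.

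In 2 pairs of labelled replicates the samples were closer to each other than the arrays within each sample. When the dye-swap arrays of these samples were exchanged, the variance between partner arrays fell to 0.589 of its labelled value in telavancin 60 min and further in enduracidin 60 min (0.370). With exchanged arrays the variance between samples was 2.32 times the technical variance or more. These values are partly tied to the closeness by which the pairs were picked. The variance between samples was 0.065 as labelled and 0.165 with exchanged arrays in telavancin 60 min. In enduracidin 60 min it was 0.041 and 0.206. One RNA hybridised as 2 samples would give equal values if the noise of the arrays were independent, which was not checked. Under that condition the values argue against one RNA. Arrays exchanged in labelling would give such values, but were not shown directly and stay open. No biological explanation was tested. In the deposited value table, enduracidin 60 min replicate 2 correlated best with the arrays of replicate 3 (0.966) and replicate 3 with those of replicate 2 (0.971).

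Telavancin 60 min replicate 1 stood apart from replicates 2 and 3, with r of 0.749 to their mean. The tables argue against noise of single arrays, since the departures of its 2 arrays from those of the other samples correlated at 0.773 or more. A sample of another group is not excluded: its r was 0.0319 higher with the mean of its own group than with that of enduracidin 60 min (0.717), but with single samples it was 0.742 and 0.752 in its own group against 0.752 with enduracidin 60 min replicate 3 and 0.742 with vancomycin replicate 1. This test was run in more than 1 form: another compared its r with each other group mean to the lowest r within that group (lower by at least 0.133), and was dropped because it leaves out how the sample relates to its own group. A difference between cultures stays open, as no label describes one, and no biological explanation was tested. A structure across groups also stays open. The deviation of this sample from its group mean correlated with those of telavancin 15 min replicate 2 (0.532) and vancomycin replicate 1 (0.423). With replicate 3 of these groups it was at -0.509 and -0.501.

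The difference between telavancin and vancomycin at 60 min correlated across tags with the response to CCCP at 0.461, over the tags with a ratio in every replicate of these groups. This takes the direction of CCCP from the names of its arrays. Turned the other way, the correlation is -0.461, every other sign given here for CCCP is reversed, and the rising and falling sets are exchanged. A bias that depends on signal did not account for it: given the mean signal on both platforms the correlation was 0.394. With 1 labelled sample left out, the lowest correlation was 0.395. Leaving out telavancin 60 min replicate 2 or 3 gave 0.459 or 0.463, but kept the other sample of this close pair. The replicate that they form was never left out, so it is not excluded as the source. As sets, the 167 tags that rose with CCCP were higher after telavancin (adjusted p = 0.014 by limma's camera with an estimated correlation, median difference 0.44). For the 222 that fell the adjusted p was 0.0641 with an estimated correlation (median difference -0.40). The answer for the falling set depended on the test. Camera with a preset correlation of 0.01 gave an adjusted p of 3.17e-06, and limma's fry gave 0.00214. The relation was not particular to telavancin or to this comparison. The change from 15 to 60 min correlated with CCCP at 0.411 for telavancin and 0.347 for enduracidin. For telavancin it shares the telavancin 60 min samples with the first difference, and what this overlap alone would give was not computed. For enduracidin it shares no sample with that difference. The adjusted p was 0.014 and 0.0426 for the rising set and 0.0896 and 0.111 for the falling set, each with an estimated correlation. Vancomycin minus enduracidin at 60 min, which shares the vancomycin samples with the first difference, correlated at -0.42 (adjusted p of 0.014 and 0.0637), whereas telavancin minus enduracidin correlated at 0.0985 at 60 min, with adjusted p of 0.222 and 0.63 for the rising and falling sets with an estimated correlation, and at -0.118 at 15 min, with adjusted p of 0.261 and 0.384. The falling sets of vancomycin minus enduracidin and of both time differences passed 0.05 by the preset form and by fry. For telavancin minus enduracidin at 60 min the rising set had an adjusted p of 0.0324 by the preset form and 0.221 by fry. Doses differed between compounds, and their effect was not tested.

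Other splits were counted for groups with 3 replicates. With 1 of the 4 sign patterns real, telavancin 15 min called 694 tags against 24 in the highest other pattern, vancomycin 906 against 58 and enduracidin 15 min 684 against 31. In each case 1 pattern reached the real count, and 4 patterns are too few for a share under 0.05. For telavancin against enduracidin at 15 min the real count was 0, which every split reaches whatever the data. That 10 of 10 splits did so, the highest other being 0, therefore decides nothing.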

How the results depend on the processing

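Counting close samples as 1 replicate, on which the reported counts rest, was chosen after the counts with and without it had been seen; the plan had counted all 15 samples, so that setting is the planned one and was listed as an alternative only after seeing the data. The floor for spots at 0, the filter on control spots, exchanging dye-swap arrays, the block over all 15 samples, exchanging columns of the value table and turning CCCP were also chosen after seeing the data. The other alternatives were listed before the data were examined, but those on the larger platform were run with the close samples counted as 1. No background subtraction, normexp with offset 0, a dim-spot filter on background and slide or scan batches were not run. The reasons were that the intensities were taken as already corrected and that the files give no usable background or date. The 25 gene lists matched no tag and were not tested. CCCP with 1 sample left out has no residual degrees of freedom. A ratio was obtained for 1602 to 2675 of 4272 tags per sample, because spots at 0 were left out and both dye orientations were required. Keeping only spots above the control spots tested fewer tags, for example 1443 against 1873 for telavancin 15 min. Apart from turning CCCP, of 177 counts under settings other than leaving out a sample, 115 stayed within 1.5 times, as did 145 of 180 with a sample left out, and 0 called tags were called with the opposite sign. Counts of similar size need not hold the same tags. Of the 229 for telavancin against vancomycin, 184 were called again with median centring, 146 with print-tip loess and 66 with the deposited value table. Of the 121 for vancomycin against enduracidin, 45 were called again with that table, which called 83. Fewer tags were tested with that table. The cause of the larger shifts was not tested, except where fewer tags, fewer samples or a stricter threshold enter by construction. Spread was unequal, though. The variance of the difference between samples was 1.115 and 1.175 for telavancin 60 min replicate 1 against the others. Within enduracidin 60 min it was 0.041 to 0.191. The shared estimate of the spread may thus be too small for telavancin 60 min, and its counts of 229 and 399 too high. Fits of the groups alone also rest on fewer samples.

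With the deposited value table the counts against untreated were 386 for telavancin 15 min, 589 for telavancin 60 min, 481 for vancomycin, 354 for enduracidin 15 min, 557 for enduracidin 60 min and 340 for CCCP, and those of the differences were 110 for telavancin against vancomycin, 2 for telavancin against enduracidin at 15 min, 197 for the times of telavancin and 122 for the times of enduracidin. It moved the share of higher tags from 37.6% to 60.9% for telavancin against vancomycin, from 35.1% to 54.8% for the times of telavancin and from 34.1% to 49.2% for those of enduracidin. With its enduracidin 60 min columns of replicates 2 and 3 exchanged, the table gave 378 for telavancin 15 min, 575 for telavancin 60 min, 477 for vancomycin, 346 for enduracidin 15 min and 543 for enduracidin 60 min, and for the differences 101 for telavancin against vancomycin, 1 for telavancin against enduracidin at 60 min and 2 at 15 min, 56 for vancomycin against enduracidin, 179 for the times of telavancin and 93 for those of enduracidin. At least 2-fold changes numbered 404 for telavancin 15 min, 576 for vancomycin and 400 for enduracidin 15 min. Only the groups of the comparison gave 553 for telavancin 60 min, 1051 for enduracidin 15 min, 4 for telavancin against vancomycin, 0 for telavancin against enduracidin at 60 min and 13 at 15 min, 125 for the times of telavancin and 640 for those of enduracidin. Arrays with the treated RNA in Cy3 gave 148 for telavancin against vancomycin, 3 for telavancin against enduracidin at 60 min and 128 for the times of enduracidin. Arrays with it in Cy5 gave 1 for telavancin against enduracidin at 60 min, 4 at 15 min and 80 for vancomycin against enduracidin. Print-tip loess gave 2 for telavancin against enduracidin at 60 min.

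Keeping spots at 0 at a floor gave 1 for telavancin against enduracidin at 60 min and 460 for CCCP. Spots above the control spots gave 626 for telavancin 60 min, 0 for telavancin against enduracidin at 60 min, 2 at 15 min, 1 for the interaction and 347 for CCCP. All 15 samples counted gave 754 for telavancin 15 min, 1214 for telavancin 60 min and 971 for vancomycin against untreated. For enduracidin they gave 762 at 15 min and 1269 at 60 min. For the differences they gave 362 for telavancin against vancomycin, 67 for telavancin against enduracidin at 60 min and 0 at 15 min. Counts were 282 for vancomycin against enduracidin, 604 for the times of telavancin, 414 for those of enduracidin and 3 for the interaction. Exchanged dye-swap arrays with all 15 samples counted gave 46 for telavancin against enduracidin at 60 min, 250 for vancomycin against enduracidin, 357 for the times of enduracidin and 2 for the interaction.

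Samples with the same replicate number did not always deviate together. Over 30 such pairs across groups the correlation ranged from -0.50 to 0.47, and 12 were over 0.1. The median was 0.062, against -0.004 for pairs with different numbers. Some pairs with different numbers also deviated together, as telavancin 15 min replicate 2 with telavancin 60 min replicate 1 at 0.532. Telavancin 15 min replicate 3 with that last sample was at -0.509. A structure across groups is not excluded, its cause was not tested, and the main fit has no term for it. With the replicate block and all 15 samples counted, the counts were 369 for telavancin against vancomycin, 49 for telavancin against enduracidin at 60 min and 1 at 15 min, 264 for vancomycin against enduracidin (140 higher and 124 lower), 618 for the times of telavancin, 400 for those of enduracidin and 4 for the interaction.

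With 1 sample left out, counts ranged from 395 to 795 for telavancin 15 min, 884 to 982 for telavancin 60 min, 547 to 1034 for vancomycin, 263 to 821 for enduracidin 15 min and 538 to 1075 for enduracidin 60 min. For the differences they ranged from 129 to 233 for telavancin against vancomycin, 0 to 10 for telavancin against enduracidin at 60 min and 0 to 10 at 15 min, 32 to 224 for vancomycin against enduracidin, 265 to 450 for the times of telavancin and 75 to 350 for those of enduracidin, and stayed at 0 for the interaction. Leaving out 1 sample of a close pair kept the other, so the replicate that they form was never left out. The ranges therefore do not show how far counts of telavancin 60 min and enduracidin 60 min depend on that replicate. CCCP turned to untreated over treated keeps 694 called tags, all in the opposite direction, and gives correlations of -0.265 with telavancin 15 min, -0.473 with telavancin 60 min, -0.226 with vancomycin, -0.31 with enduracidin 15 min and -0.459 with enduracidin 60 min. Under the other settings run for them, correlations between groups moved by no more than 0.1.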

Other observations

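The test of neighbouring tags was chosen after their correlation was seen. Tags with consecutive numbers were often called together. After telavancin 60 min, 302 of 945 called tags stood beside a tag called in the same direction, against a mean of 147.1 when calls were shuffled among tags. After enduracidin 60 min 292 of 965 did, against 144.7, and after CCCP 208 of 693, against 83.9. In 0 of the 6 comparisons against untreated did any of 1000 shuffles reach the observed number, which argues against a chance order of tags. The tag numbers were taken from the files, and no genome was used to check that consecutive tags are adjacent.

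The longest run after enduracidin 60 min was of 10 lower tags, from SACOL2220 to SACOL2229, with log2 ratios between -2.83 and -1.69. The same series of tags, from SACOL2220 to SACOL2226, held 7 lower tags after vancomycin, between -1.39 and -0.90. After telavancin 60 min 7 lower tags ran from SAV0186 to SAV0192, between -3.54 and -0.91. A run of 5 higher tags, from SAS0525 to SAS0529, was the longest higher run after telavancin 60 min, vancomycin and enduracidin 60 min, with ratios of 1.07 to 1.77, 0.81 to 1.05 and 0.88 to 1.97. These runs were chosen after their values were seen.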
